A study of Homo sapiens with 5 samples.

How the data were processed

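Total RNA of SNU668 gastric cancer cells was labelled and hybridised to 5 arrays, per the labels' protocols: sense cDNA was fragmented and labelled with biotin by terminal transferase with a GeneChip whole-transcript kit. The deposited series table holds 1 value per probe set and array. Its values are log2 signals, judged from their range, and no unit, background correction, summarization, normalization or software of the authors is given in the sources used here. The medians of the arrays after row recovery were 4.47 (untreated), 4.49, 4.32 and 4.32 (CAF co-culture replicates 1 to 3) and 4.28 (GAS6), so the values were not centred by gene, and their exact scaling stays unknown. Groups were taken from the sample titles and treatment labels, and co-culture replicates were numbered in accession order, which pairs them with nothing. The shared treatment protocol of the labels mentions only GAS6 protein, including for the co-cultures, so the co-culture labels of each sample were followed.

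The row order of the deposited table was examined before any test. The column of CAF co-culture replicate 1 was filled in all 53617 rows, and the other 4 columns in the first 48416 rows only. As deposited, replicate 1 did not correlate with the untreated array (r = -0.00), while the other 4 correlated with each other at 0.934 or above. Aligning the untreated column to replicate 1 with a dynamic programming alignment (affine gaps, opening cost 20) showed that 5201 rows had been left out of the other 4 columns in blocks, beginning with the first 3575 rows, with the remaining values moved up. A second alignment, on the mean of the other 3 short columns, placed 48337 rows (99.8%) in the same way, and only these rows were used. After alignment the untreated array correlated with replicate 1 at 0.991. The median over ribosomal protein genes, which every cell transcribes strongly, was 4.46 in the untreated array as deposited and 7.22 after alignment, against 7.08 in replicate 1. Tested on simulated tables of 8000 rows with 831 left out, the alignment recovered 99.99% and 99.93% of rows at noise of 0.1 and 0.6 log2 units. This correction was chosen after seeing the data, and counts from the rows as deposited are given with the alternatives.

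Of 53617 probes, 16098 had 1 gene symbol in the annotation table, 0 had several and 37519 were unnamed here. All 16098 matched the RefSeq gene table of assembly GRCh38.p14 by Entrez identifier, with 0 symbols changed, and 16032 had an aligned row. No coordinates are given. For a gene with several probes the probe with the highest mean stood for it, which left 14815 genes. A gene was tested when its mean over the 5 arrays exceeded the 30th percentile of all probes (3.42), which left 12812. Genes of the Y chromosome and the X-inactivation transcripts were left out.

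CAF co-culture was compared with untreated and with GAS6 in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 1 mean per group, Benjamini-Hochberg adjustment, threshold 0.05). Only the CAF group has replicates, so the fit has 2 residual degrees of freedom (prior 2.31), and the single untreated and GAS6 arrays were assumed to vary like the co-cultures. GAS6 was compared with untreated without a test, by counts of genes at 2-fold or more, and as an alternative in limma on the spread of the co-cultures. The 26 gene lists, with 479 entries of which 265 were measured, were fixed before the data were examined. They were tested with camera at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry. For GAS6 against untreated the median of each list was set against 10000 random lists matched on mean expression in 20 bins, and called outside under the 2.5th or over the 97.5th percentile. Arrays were put into sets by the share of exactly equal values, without the group labels, and the set was added to the fit as a block (1 residual degree of freedom).

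The genes named were fixed by rule before the data were examined. They are AXL, TYRO3, MERTK, GAS6 and PROS1 throughout; the 12 largest differences of each sign, called and of the same sign in all 3 arrays, for CAF against untreated; the 12 largest of each sign for GAS6 against untreated; the 10 largest of each sign for CAF against GAS6; and up to 4 members of each list per comparison. Where fewer than 5 genes passed the test in a direction, which was so in every case, the largest of that sign in all 3 arrays were named as not passing. Small and many non-coding RNA, unnamed locus, immune receptor segment and olfactory receptor symbols (1037 tested genes) were counted but not named by these rules, which go by symbol prefix and so let the pseudogene HAVCR1P1 and the non-coding RNAs UCA1, RAB11B-AS1 and PCED1B-AS1 through. List members beyond these, and genes named for their values within an array set, were chosen after the values were seen.

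The tests were run first on simulated data with 200 of 12812 genes changed. With the spread of the 3 CAF arrays, 0% of genes changed by 1, 2 or 4 log2 units were called between CAF and untreated, although 44.8%, 71.6% and 98.5% had an unadjusted p under 0.05. With the smaller spread of set 2 and no set difference, 100% were called at each size, with 37 false calls, more than the threshold would allow. With a simulated set difference and the set as a block, 97.0%, 100% and 100% were called, with 29 false calls. In these simulations the spread given to the arrays, not their number alone, decided the count of calls. The spread of set 2 had been moderated across genes before the noise was drawn. The simulations therefore do not show what limited the calls in the measured arrays. The alternatives were quantile normalization, centring on array medians, no dim filter or one at the 50th percentile, the mean of a gene's probes, an intensity trend or robust eBayes, a 2-fold minimum, a 1.5-fold count, only the groups compared, and leaving out each CAF array. Chosen after seeing the data were the rows as deposited and array set as a block. Alignment, tests of explanations and figures used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.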

Results

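Transcript levels were measured on 5 whole-transcript GeneChip arrays of SNU668, an established human gastric cancer cell line. Of these, 1 array came from untreated cells, 3 came from cells co-cultured with cancer-associated fibroblasts (CAFs, the activated fibroblasts of tumour stroma) and 1 came from cells given recombinant human GAS6 protein. GAS6 is a secreted ligand of the receptor tyrosine kinases TYRO3, AXL and MERTK, together called TAM receptors, and the series concerns GAS6/AXL signalling and the response to chemotherapy. The sample titles give each co-culture its own fibroblast number without saying what the numbers stand for, and the sources do not say whether the fibroblasts were kept apart from the cancer cells. The spread between the co-cultures thus includes any difference between their fibroblasts, and every p-value measures only the spread between these arrays. The untreated and GAS6 groups had no replicates, and the number of arrays limits the precision.

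A pair of technical features of the table bears on every comparison. Its values were in the order of its probe identifiers only for CAF co-culture replicate 1, and the row order of the other 4 arrays was recovered by aligning them to that array. After this step the 5 arrays also fell into 2 sets by the form of their values. Set 1 held the untreated array and CAF co-culture replicate 1, which had exactly equal values at 54.7% of 48337 probes. Set 2 held CAF co-culture replicates 2 and 3 and the GAS6 array, of which no pair was exactly equal at more than 0.265% of probes. Across all probes the Pearson correlation was 0.991 within set 1, 0.991 to 0.992 within set 2 and 0.929 to 0.936 between the sets. Comparisons that stay within a set are therefore given beside those that cross it, and this split was made after the data were seen. Of the 12812 genes tested, 250 differed 2-fold or more between the untreated array and replicate 1, 27 between replicates 2 and 3, and 3777 and 3664 between replicate 1 and replicates 2 and 3. The median of all genes lay 0.22 above untreated on the log2 scale for the CAF mean and 0.35 above it for GAS6, and lay 0.15 lower for the CAF mean than for GAS6. Quantile normalization brought these medians to -0.01, -0.01 and -0.01.

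The receptor and ligand of the pathway under study were examined first. AXL transcript was abundant in untreated cells, at 9.71 log2 units, and measured 10.28, 11.11 and 11.19 in the 3 CAF co-cultures and 11.13 after GAS6 protein. The CAF mean lay 1.15 ± 0.50 (SE) log2 units above untreated, in 3 of 3 arrays, which did not pass the test (limma, adjusted p = 0.814), and within set 1 the difference was 0.57. After quantile normalization the difference of AXL from untreated was 0.29 for the CAF mean and 0.14 for GAS6. GAS6 transcript was at 5.84 in both arrays of set 1 and at 9.10, 9.11 and 9.07 in the arrays of set 2. PROS1, a further ligand of the TAM receptors, had the same form, with 3.99 in both arrays of set 1 and 5.71, 5.61 and 5.49 in set 2. TYRO3 ranged from 5.42 to 5.96 and MERTK from 4.55 to 4.85 over the 5 arrays. GAS6, PROS1, TYRO3 and MERTK were exactly equal in the 2 arrays of set 1, as were 54.7% of all probes. The source of these ties is unknown, so they do not show that co-culture left these genes unchanged.

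**Figure D1:**
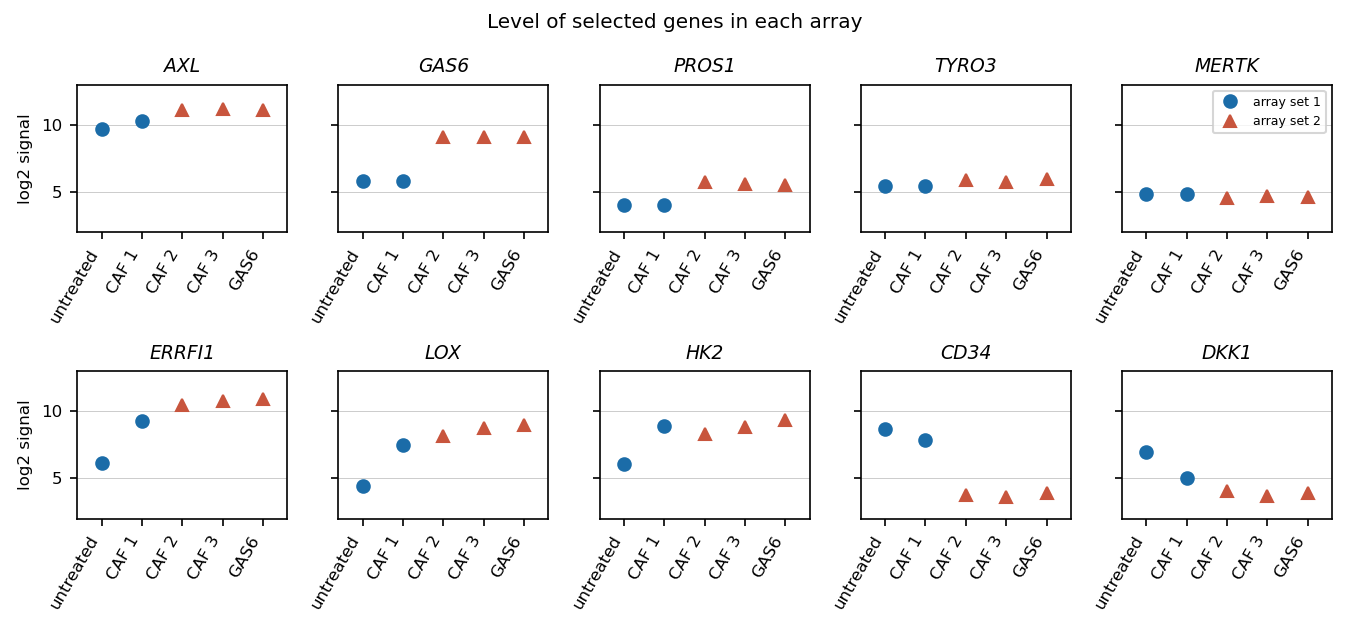
Log2 signal (vertical axis) of 10 genes in each of the 5 arrays (horizontal axis: untreated, CAF co-culture replicates 1 to 3, GAS6), 1 point per array, with circles for array set 1 and triangles for array set 2. GAS6 and PROS1 split by array set, while ERRFI1, LOX and HK2 in CAF co-culture replicate 1 lie above the untreated array of the same set (ERRFI1 9.25 against 6.16).

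Co-culture with CAFs was then compared with untreated cells. The gene with the largest difference in the same direction in all 3 CAF arrays was NRN1, the gene of the neurotrophic factor neuritin, which measured 4.14 in untreated cells and from 6.15 to 12.14 in the co-cultures. ERRFI1, a feedback inhibitor of the EGF receptor, was 4.01 ± 0.70 (SE) log2 units higher in the co-cultures, with 3.10 in replicate 1, and LOX, a collagen-crosslinking enzyme, was 3.71 ± 0.59 (SE) higher, with 3.03 in replicate 1. The other genes named for the largest excess over untreated were COXFA4L3 (4.91), RTN4RL2 (3.66), TMEM45A (3.38), the polyamine-degrading enzyme SAT1 (3.31), PLAC8 (3.20), RAB11B-AS1 (3.19), the small GTPase RHOB (3.07), ECEL1 (3.04) and SOCS3 (2.89), a feedback inhibitor of JAK-STAT3 signalling. Of the genes lower in all 3 co-cultures, CD34 fell short of untreated by the most, with a log2 difference of -3.61 ± 1.91 (SE), followed by RANBP3L (-2.72) and the secreted Wnt antagonist DKK1 (-2.68 ± 0.61, SE). OSBPL6 (-2.26), PARM1 (-1.91), FREM2 (-1.90), HERC6 (-1.88), SAMD9 (-1.87), TMX4 (-1.87), the basement membrane gene NID1 (-1.84), ETNPPL (-1.72) and the ephrin receptor EPHA4 (-1.65) completed the lower group.

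None of these genes passed the test. The fit in limma with Benjamini-Hochberg adjustment called 0 of 12812 genes at an adjusted p under 0.05, the smallest adjusted p being 0.814, and 128 genes had an unadjusted p under 0.05 (108 higher and 20 lower). The CAF mean differed 2-fold or more from untreated at 1570 genes, of which 1446 were higher and 124 lower. After quantile normalization these were 459 higher and 350 lower, and the unadjusted calls were 132 higher and 146 lower. A difference of 2-fold or more in the same direction in all 3 co-cultures was found for 80 genes, 76 higher and 4 lower. Replicate 1 decided the count of calls: without it, 7250 genes passed (5628 higher and 1622 lower), in a comparison of arrays of set 2 with an untreated array of set 1. With array set as a block, 0 genes passed and 1144 had an unadjusted p under 0.05, and the estimate then rests on replicate 1 against untreated, where 124 genes were 2-fold or more higher and 126 lower. The single untreated array was assumed to vary like the CAF arrays.

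Gene lists fixed before the data were examined gave 9 calls among 26 lists with limma's camera at a preset inter-gene correlation of 0.01, 5 higher and 4 lower. After quantile normalization the balance was the other way, with 2 lists higher and 6 lower. The hypoxia and glycolysis list rose (median log2 difference 1.05, adjusted p = 9.10e-08, and 0.84 with an estimated correlation), with 10 of 11 measured members higher in all 3 co-cultures. HK2, the hexokinase that starts glycolysis, was 2.64 ± 0.39 (SE) higher, the vasodilator peptide gene ADM 2.16, the mitophagy gene BNIP3 1.91 and the oxidoreductase ERO1A 1.61. Its members passing on a p adjusted over the list alone numbered 1, and over all genes 0. Within set 1 the median was 1.10. Without replicate 1 the call was lost, with medians of 0.73 and 0.95 in replicates 2 and 3 that lay at the 28.9th and 57.8th percentile of random lists. The JAK-STAT3 target list rose as well (median 1.16, adjusted p = 6.54e-05, and 0.84 with an estimated correlation), with 9 of 10 members higher in all 3 co-cultures: SOCS3 (2.89), the transcription factor JUNB (2.08), BCL3 (1.85) and the oncostatin M receptor OSMR (1.28). Within set 1 its median was 0.65, and SOCS3 was 0.94 higher.

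The other 3 rising lists did so by smaller margins. The unfolded protein and integrated stress response list had a median of 0.76 (adjusted p = 0.0352, and 0.84 with an estimated correlation), with SDF2L1 2.55, VLDLR 1.93 and DDIT4 1.90 higher, and a median of 0.02 within set 1. The anti-apoptotic list had a median of 0.73 (adjusted p = 0.042, and 0.84 with an estimated correlation), led by MCL1 (1.27), BCL2L1 (0.98) and BCL2 (0.93), and a median of 0.11 within set 1. The drug transport and drug metabolism list had a median of 1.00 (adjusted p = 0.0483, and 0.84 with an estimated correlation), led by cytidine deaminase CDA (2.40), the glutathione transferase GSTP1 (1.51) and the vault protein MVP (1.42), and a median of 0.21 within set 1. Under quantile normalization or with array set as a block none of these 3 lists was called. Set against 10000 random lists of like expression, the hypoxia median lay above the central range (98.6th percentile). The medians of the other 4 rising lists lay inside it, at percentile 96.8 for JAK-STAT3 targets, 93.8 for the stress response, 92.0 for anti-apoptotic genes and 91.9 for drug transport and metabolism.

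The remaining 4 called lists fell relative to other genes. Fibroblast markers had a median of -0.23 (adjusted p = 0.0281, and 0.84 with an estimated correlation), with LUM -1.70, FBN1 -1.19 and VCAN -0.61, while FBLN1 was higher in set 2 (8.32 to 8.38) than in set 1 (6.56). Within set 1 their median was 0.00, with 6 of 12 members exactly equal in both arrays, and the block fit turned their direction to higher (adjusted p = 0.0255, and 0.639 with an estimated correlation), with FN1 2.31 higher in replicate 1 than in untreated cells. After quantile normalization this list was not called. Stem cell markers had a median of -0.42 (adjusted p = 0.0281, and 0.84 with an estimated correlation), with POU5F1 -1.18, SOX9 -0.74 and SOX2 -0.69, and a median of 0.00 within set 1, where 4 of 6 members were exactly equal. For interferon-stimulated genes the test pointed lower (adjusted p = 0.0281, and 0.84 with an estimated correlation) while the median was 0.02, with HERC6 -1.88, IFIT2 -1.48, IFIH1 -1.17 and IFIT3 -0.83, and a median of -0.14 within set 1. DNA replication genes had a median of -0.19 (adjusted p = 0.0352, and 0.84 with an estimated correlation), with MCM10 -0.97, CDC6 -0.76 and MCM3 -0.70. Among random lists the medians of DNA replication (percentile 0.00), stem cell markers (0.48) and fibroblast markers (1.22) lay below the central range, and that of interferon-stimulated genes inside it (24.9). No list was called when camera estimated the inter-gene correlation, and fry, which tests a list without reference to other genes, gave adjusted p from 0.557 to 0.986 over the 26 lists.

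Within set 1 the list with the largest median difference was DNA replication, followed by hypoxia and glycolysis and then G2/M genes. With array set as a block, DNA replication genes were lower in CAF co-culture replicate 1 than in untreated cells by a median of -1.47 (camera adjusted p = 2.07e-34, and 0.639 with an estimated correlation), and none of the 22 measured members was higher. The helicase loader CDC6 differed by -2.41, GINS2 by -2.29, MCM10 by -2.06 and MCM3 by -1.64. G2/M genes differed by a median of -1.03 (adjusted p = 8.44e-25), with MKI67 at -1.10, and DNA repair genes by -0.48 (adjusted p = 3.17e-07). The hypoxia list was called higher in the same fit (median 1.10), as were JAK-STAT3 targets (0.65). Mesenchymal transition genes (median 0.04) and CAF-secreted factors (0.02) were called higher through few members. In the first, LOX (3.03) and LOXL2 (1.01) differed most, and 4 of 8 members were exactly equal in the 2 arrays. In the second, STC1 (2.04) and IL11 (1.46) differed most, and 4 of 11 members were exactly equal. Cholesterol synthesis genes (median -0.20) and interferon-stimulated genes (-0.14) were called lower. These p-values rest on 1 residual degree of freedom and 1 array per group within the set, and with an estimated correlation the adjusted p was 0.639 for each of the 10 lists called in this fit. The residual of that fit is the difference between replicates 2 and 3, so no spread within set 1 enters the p-values. Camera also sets each list against the other genes, many of which were exactly equal in set 1. In replicates 2 and 3 the replication medians were 0.77 and 0.24 above the untreated array of the other set.

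**Figure D2:**
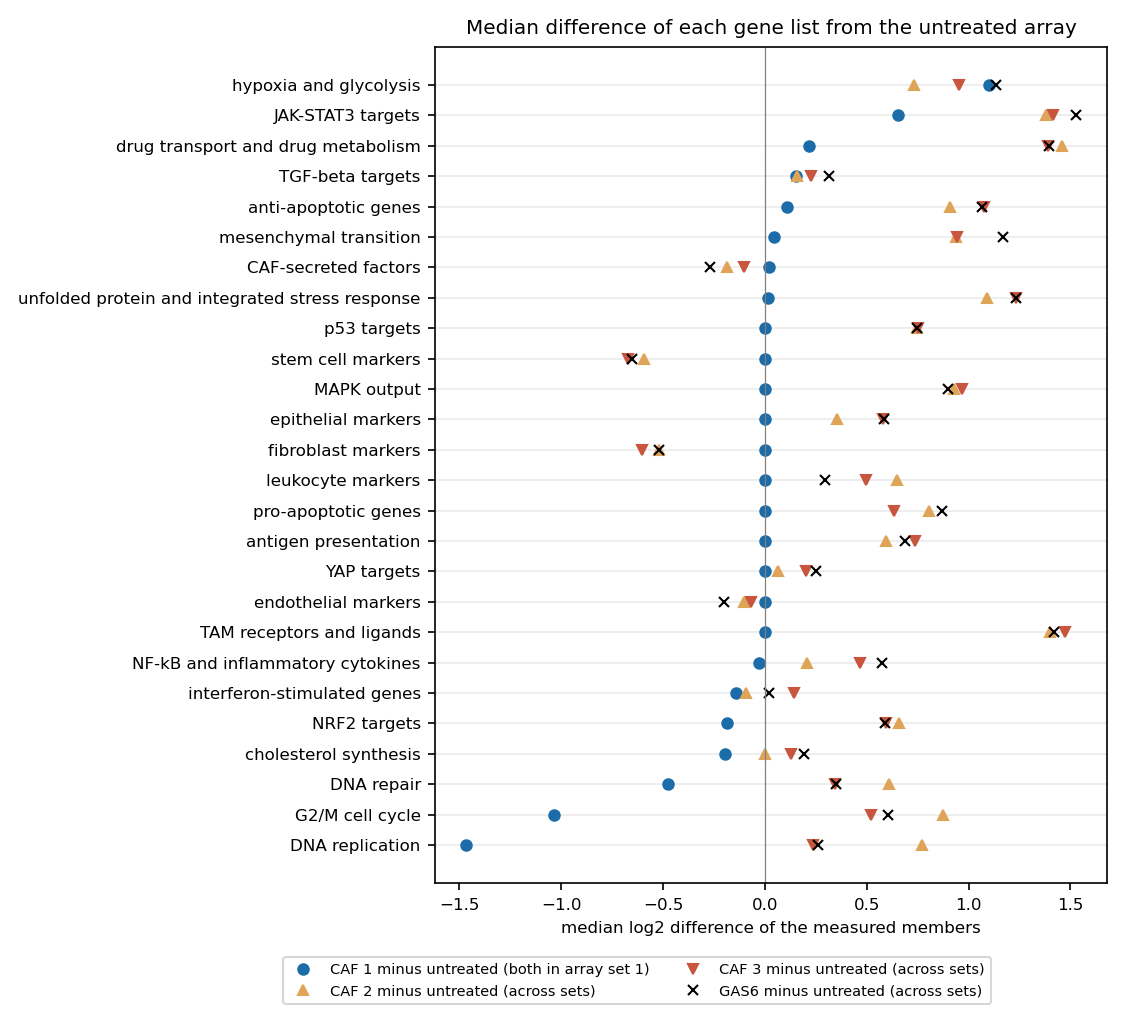
Median log2 difference from the untreated array (horizontal axis) over the measured members of each of the 26 gene lists (vertical axis), 1 point per array: CAF co-culture replicates 1, 2 and 3 and GAS6. CAF co-culture replicate 1 lies apart from the other 3 arrays for DNA replication (-1.47 against 0.77, 0.24 and 0.26), and all 4 lie between 0.73 and 1.14 for hypoxia and glycolysis. Among random lists of like expression the hypoxia median lay at percentile 100 for replicate 1. For replicates 2 and 3 and GAS6, which cross the array sets, it lay inside, at 28.9, 57.8 and 75.6. The random lists had a median of 0 for replicate 1, where many values were exactly equal to those of the untreated array. For replicates 2 and 3 and GAS6 they had medians of 0.896, 0.88 and 0.917. These percentiles thus rest on different backgrounds and do not show that replicate 1 stands apart for hypoxia and glycolysis.

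The other 17 lists were not called in the comparison of CAF co-culture with untreated cells, with adjusted p from 0.0927 to 0.896. Their medians were 1.11 for TAM receptors and ligands, 0.73 for mesenchymal transition, 0.68 for MAPK output, 0.53 for pro-apoptotic genes, 0.50 for p53 targets, 0.42 for antigen presentation, 0.35 for NRF2 targets, 0.30 for epithelial markers, 0.29 for leukocyte markers, 0.22 for NF-kB and inflammatory cytokines, 0.22 for TGF-beta targets, 0.17 for DNA repair, 0.15 for G2/M genes, 0.11 for YAP targets, -0.00 for cholesterol synthesis, -0.05 for CAF-secreted factors and -0.10 for endothelial markers. Among random lists of like expression, the medians of G2/M genes (percentile 0.01), cholesterol synthesis (0.06) and YAP targets (0.88) lay below the central range and that of TAM receptors and ligands above it (99.7). Within set 1 the TAM median was 0.00 (50.2nd percentile), with 4 of 5 members exactly equal. Within the mesenchymal transition list LOX was 3.71 and the crosslinking enzyme LOXL2 1.44 higher, and the intermediate filament gene VIM measured 7.71 in untreated cells and 7.80, 9.83 and 9.92 in the co-cultures. Among CAF-secreted factors, STC1 was 2.29 ± 0.38 (SE) higher and the matrix protein gene TNC measured 9.96 in both arrays of set 1 and 6.65 and 6.67 in replicates 2 and 3.

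GAS6 protein treatment was next compared with the untreated array. Limma on the spread of the co-cultures was run only as an alternative, given with the other settings. The main comparison used no test, because each group had 1 array, and the difference has no replicate check. It also lies wholly across the 2 array sets, so treatment and set cannot be told apart in it. At 2-fold or more, 3144 genes were higher and 494 lower after GAS6, and quantile normalization made these 1148 and 919. The largest excesses over untreated were those of NRN1 (8.09), COXFA4L3 (6.78), the insulin-like growth factor binding protein IGFBP7 (5.74), the complement receptor C5AR1 (4.93), the formyl peptide receptor FPR1 (4.84), ERRFI1 (4.75), LOX (4.56), the secreted Wnt antagonist FRZB (4.55), the glypican GPC3 (4.49), RTN4RL2 (4.47), EDARADD (4.42) and GPR183 (4.31). The largest deficits were those of the long non-coding RNA UCA1 (-5.12), CD34 (-4.77), RANBP3L (-3.86), TNC (-3.38), NID1 (-3.02), DKK1 (-3.00), KLF12 (-2.89), PARM1 (-2.88), the alarmin IL33 (-2.84), FREM2 (-2.77), ARID5B (-2.70) and OSBPL6 (-2.65). For IGFBP7, C5AR1, FPR1, GPC3, EDARADD and GPR183, CAF co-culture replicate 1 differed from untreated by 0.00, 0.00, -0.01, 0.00, 0.00 and 0.00, and CAF co-culture replicates 2 and 3 differed from GAS6 by 0.03, 0.15, 0.08, 0.28, 0.05 and 0.45 on average. A difference of 0.00 in set 1 does not show an unchanged transcript, since 54.7% of all probes were exactly equal in its 2 arrays. With array set as a block, the estimate for 12 of the 29 genes compared here changed sign, and 393 genes differed 2-fold or more (191 higher and 202 lower). In that fit the untreated and GAS6 arrays are linked only through the co-cultures. The estimate is replicate 1 minus untreated, less the difference of replicates 2 and 3 from GAS6. Where the 2 arrays of set 1 were exactly equal, as for GAS6 and PROS1 transcript, it holds only the difference within set 2. A change of sign in such a gene is no measure of GAS6 treatment against untreated.

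Of the 26 lists, 7 had a median outside the central range of 10000 random lists of like expression in the GAS6 array against untreated, 1 above and 6 below. With array set as a block 9 lists lay outside, 4 above and 5 below. That estimate carries the difference of CAF co-culture replicate 1 from untreated. Of the 7 lists only G2/M, DNA replication and cholesterol synthesis were outside there too. Their block medians were -1.15, -1.76 and -0.23, against -1.03, -1.47 and -0.20 for replicate 1 minus untreated. Without the block these medians had the opposite sign. Without the block, TAM receptors and ligands lay above the central range (median 1.42, 99.2nd percentile), through GAS6 transcript (3.23), PROS1 (1.49) and AXL (1.42). Under quantile normalization AXL was 0.14. With array set as a block the TAM median was -0.00 (53.5th percentile), with AXL at 0.55, TYRO3 at 0.15, MERTK at -0.00, GAS6 at -0.03 and PROS1 at -0.18. For the 4 members exactly equal in set 1, all but AXL, these block values hold only the difference within set 2. Below the central range, without the block, were fibroblast markers (median -0.52, percentile 0.22), stem cell markers (-0.65, 0.56), YAP targets (0.25, 0.84), G2/M genes (0.61, 1.00), DNA replication (0.26, 0.05) and cholesterol synthesis (0.19, 0.50). The medians of the last 4 were above untreated by less than those of genes of like expression, whose random lists had medians of 0.88, 1.08, 0.92 and 0.79. JAK-STAT3 targets (median 1.53, 87.0th percentile) and hypoxia and glycolysis (1.14, 75.6th percentile) lay inside the range, with SOCS3 3.71 and HK2 3.28 above untreated. As values from 1 array per group these describe the 2 arrays only.

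The differences from untreated in the CAF mean and in the GAS6 array were nearly proportional across genes (Pearson r = 0.969, Spearman rho = 0.964 over 12812 genes, which are not independent replicates). Unchanged groups sharing the single untreated array gave r = 0.611 on average over 100 simulated draws, a value that the design alone fixes. Every simulated array had the spread of the 3 CAF arrays, which includes the difference between the sets, as independent noise. The simulated covariance and counts are therefore no measure of what unchanged groups would give in these arrays. The covariance was 0.534 against 0.352 simulated, a difference of 0.182. Genes 2-fold or more higher in both numbered 1439, against 388 in the simulated draws and 355 for independent lists. Those lower in both numbered 121, against 389 simulated and 4.78 for independent lists. The single untreated array could not be split, and part of the excess may come from it and from the array set that GAS6 shares with replicates 2 and 3. The relation followed the array sets: r was 0.130 for replicate 1 and 0.962 and 0.971 for replicates 2 and 3. Replicates 2 and 3 minus replicate 1, a difference between arrays of 1 group, correlated with the GAS6 difference at r = 0.907 with no array in common. Within sets, where replicate 1 minus untreated was set against GAS6 minus replicates 2 and 3, r was 0.202. This value is no within-set form of the relation, since set 2 holds no untreated array. A response shared by GAS6 and co-culture would cancel in GAS6 minus replicates 2 and 3.

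**Figure D3:**
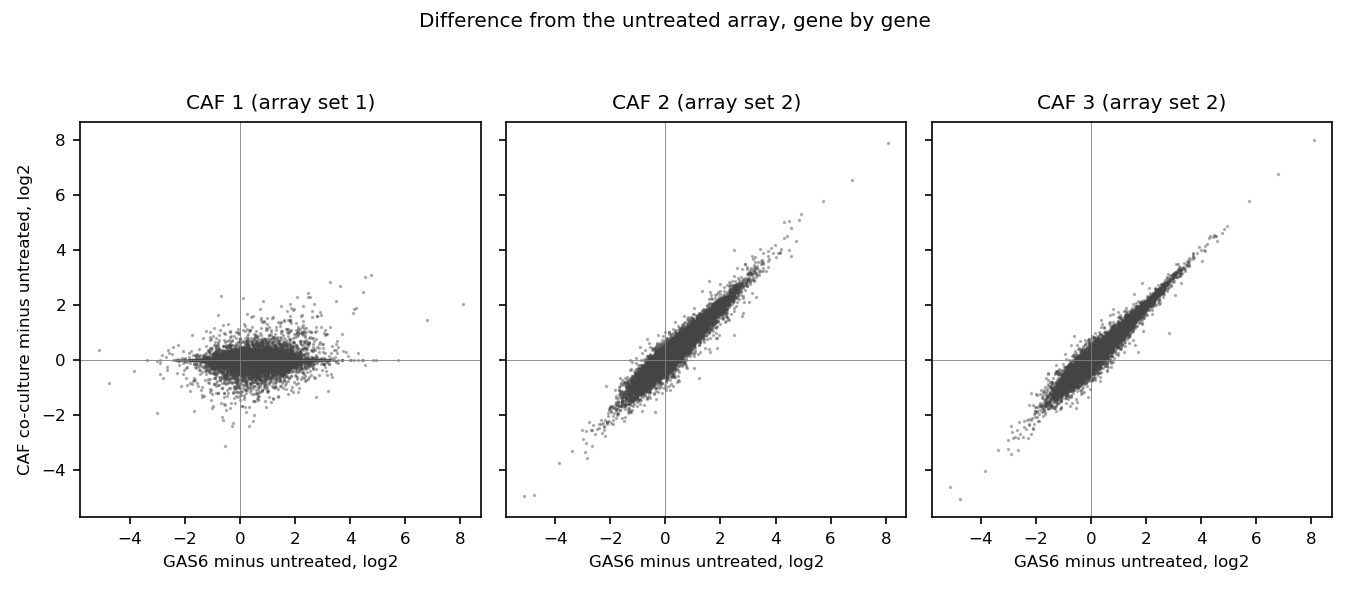
Difference from the untreated array in each CAF co-culture replicate (vertical axis, log2) against that in the GAS6 array (horizontal axis, log2), 1 point per gene for 12812 genes. CAF co-culture replicates 2 and 3, of the same array set as GAS6, follow it (r = 0.962 and 0.971), and replicate 1, of the other set, does not (r = 0.130).

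The last comparison asked which transcripts differed between co-culture and the soluble ligand. Within set 2, where the arrays can be compared directly, CAF co-culture replicates 2 and 3 and the GAS6 array differed 2-fold or more on average at 14 genes, 7 higher and 7 lower in co-culture, and 9 of the 14 were small RNAs or of other classes left out of naming. The metallothionein gene MT1E was 1.10 higher in co-culture and GCSH, of the glycine cleavage system, differed by -1.06, with 4.01 and 3.24 in replicates 2 and 3 and 4.68 after GAS6. By the mean of all 3 co-cultures, UCA1 (2.07 ± 2.36, SE), KLF12 (1.23), TNC (1.18), NID1 (1.18), ARID5B (1.04) and the growth factor gene HGF were higher than after GAS6, and within set 2 these differed by 0.35, 0.40, 0.08, 0.28, 0.16 and 0.31. XYLT1 (1.17), KRTAP5-3 (1.06) and HAVCR1P1 (1.01) kept most of their difference within set 2 (0.95, 0.84 and 0.70). Those lower by the mean of all 3 were NRN1 (-2.13 ± 2.70, SE), COXFA4L3 (-1.87), FPR2 (-1.58), PCED1B-AS1 (-1.53), SPACA6 (-1.31), HACL2 (-1.25) and EBI3 (-1.24), with -0.35 to -0.14 within set 2. ZNF350 (-1.23) kept -0.82 within set 2. The monocyte chemokine CCL2 (-1.25) varied between the co-cultures, with 5.09, 6.86 and 7.68 against 7.79 after GAS6.

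AXL, GAS6 and PROS1 differed between replicates 2 and 3 and the GAS6 array by 0.02, 0.03 and 0.18, and TYRO3 and MERTK by -0.15 and 0.00. The fit in limma called 0 of 12812 genes between all 3 co-cultures and GAS6 (smallest adjusted p = 0.998), with 8 at an unadjusted p under 0.05, and 0 with array set as a block, with 625 unadjusted. No list was called by camera, with adjusted p from 0.261 to 0.981. With array set as a block, DNA replication genes were higher in co-culture (adjusted p = 0.000304, median 0.28 within set 2) and hypoxia genes lower (adjusted p = 0.0112, median -0.18). With an estimated correlation the adjusted p was 0.959 for both. Replicates 2 and 3, which are of 1 group, differed from each other in the replication median by 0.41 and in the hypoxia median by -0.22.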

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

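Of the settings here, array set as a block and the rows as deposited were chosen after seeing the data, and the cause of each change was not tested unless stated. The 0 genes called in CAF co-culture against untreated, and the 0 called against GAS6, held under every setting run except that leaving out 1 co-culture gave 0 to 7250 genes against untreated, the 7250 (5628 higher and 1622 lower) without replicate 1. By construction that fit holds only arrays of set 2 against an untreated array of set 1. It calls 27 of the 29 genes named for that comparison. The smallest adjusted p against untreated otherwise ranged from 0.134 (block) to 1. Genes 2-fold or more apart between GAS6 and untreated numbered 2067 after quantile normalization, 393 with array set as a block, 6611 at 1.5-fold and 0 with limma on the spread of the co-cultures (160 unadjusted). The 9 lists called in CAF co-culture against untreated became 0 with an estimated correlation, 0 with fry, 0 with the rows as deposited, 0 with the block and an estimated correlation, and 2 to 12 on leaving out 1 co-culture, the 2 (fibroblast markers and JAK-STAT3 targets) without replicate 1. Between CAF co-culture and GAS6, 2 lists were called with the block and 1 to 4 on leaving out 1 co-culture, against 0 in the fit as designed. The direction of DNA replication depended on which was left out, higher without replicate 1 (adjusted p = 0.000289) and lower without replicate 2 (0.000126). With the rows as deposited, 0 lists lay outside random lists for GAS6, and the correlation of the GAS6 and CAF differences was 0.380 (0.930 to 0.974 on leaving out 1 co-culture). Genes 2-fold or more apart between co-cultures 1 and 2, 1 and 3, and 2 and 3 then numbered 8137, 8128 and 49, and the first pair and second pair had 2300 and 2217 after quantile normalization. A filter at the 50th percentile left 17 for replicates 2 and 3.

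Single genes that changed sign did so mostly with the block. For GAS6 against untreated these were GAS6 (-0.0338), PROS1 (-0.18), IGFBP7 (-0.0252), C5AR1 (-0.15), FPR1 (-0.0877), FRZB (-0.26), GPC3 (-0.28), EDARADD (-0.0547), GPR183 (-0.45), UCA1 (0.0242), IL33 (0.55) and OSBPL6 (0.19). Of these, GAS6 and PROS1 were exactly equal in the 2 arrays of set 1, so their block values hold only the difference within set 2. For CAF co-culture against GAS6 the genes that changed sign were AXL (0.0179), GAS6 (0.0338) and PROS1 (0.18), AXL after quantile normalization (0.15) and MERTK after centring on medians (-0.0224). Leaving out 1 co-culture gave -0.44 to 0.0179 for AXL, -1.60 to 0.0338 for GAS6 and -0.68 to 0.18 for PROS1, the upper value without replicate 1 each time. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers and the labels pair no samples. No signal over background was given in the sources used here, so dim genes were judged by level alone.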

Other observations

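Among the comparisons below, the order of probes, probes of 1 gene and median polish were tested as written before their results were seen, and the other tests were chosen after. The genes in the next 2 paragraphs were chosen after their values were seen, and none passed a test.

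Outside the gene lists, the genes highest in CAF co-culture replicate 1 relative to the untreated array of its set were ERRFI1, RAB11B-AS1 and RTN4RL2, followed by the lipid droplet coat gene PLIN2 (2.30), the ephrin ligand EFNA1 (2.27), MXRA5 (2.27), RHOB (2.12) and the carbonic anhydrase CA12 (2.03). PLIN2 and EFNA1 had the 3 co-cultures close together: PLIN2 measured 6.04 in untreated cells and 8.34, 8.30 and 8.55 in co-culture, and EFNA1 9.28, 9.28 and 9.53 in co-culture, 2.36 above untreated. The GAS6 array was as high, with 8.58 for PLIN2 and 9.48 for EFNA1. The lowest outside the lists were DSCC1 (-2.22), DTL (-2.19), DKK1 (-1.94), ZWINT (-1.90), CLSPN (-1.86), DNA2 (-1.82) and WDHD1 (-1.74).

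Within set 2, FOS measured 9.93 in CAF co-culture replicate 2, 8.11 in replicate 3 and 8.42 after GAS6, against 5.95 in both arrays of set 1. EGR1 measured 10.20, 8.77 and 8.91, and THBS1 8.81, 7.75 and 8.08. FOS had the largest difference of the 27 genes 2-fold or more apart between replicates 2 and 3.

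The untreated array and CAF co-culture replicate 1 had exactly equal values at 54.7% of probes. A repeated deposit of 1 hybridisation is argued against by the 250 genes 2-fold or more apart between them, more than the 43 of any pair in set 2. Median polish, a common way to summarize a probe set over arrays, may have produced the equality: in simulated probe sets without any difference between arrays it gave exactly equal values in 84.4% of probe sets over 3 arrays and 45.8% over 5, and in 0% over 2, 4 or 6. The 2 arrays of set 1 and the 3 of set 2 processed apart would give the reverse of what was seen, 0% and 84.4% equal against 54.7% and at most 0.265%, so median polish would need further arrays, not used here. Within an array, 63.84% (untreated) and 63.54% (replicate 1) of values were also shared with another probe, against 11.77% to 12.25% in set 2. The simulation did not examine ties between probe sets of 1 array, so it does not account for these. The sources do not say how the arrays were summarized, and median polish as an explanation stays open. No biological explanation was tested.

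The sets differed at 3533 to 3777 genes per pair of arrays. An order-preserving rescaling predicted fewer than 10 genes moving between the lowest 30% and the highest 10% of an array's probes, and 0 did, while a looser form with the 50th and 80th percentiles gave 10 and 8. Rescaling as the whole cause is argued against by the 2067 genes still 2-fold or more apart between GAS6 and untreated after quantile normalization, against 18 between replicates 2 and 3. The set difference of 589 pairs of probes of 1 gene correlated at 0.579 (highest of 1000 random pairings 0.115). Probes of 1 gene share a level, which random pairings break, so this does not decide on errors of row placement. Such errors are argued against for the untreated array, which shares 1 deposited row order with set 2. Its correlation with the arrays of set 2 was 0.934 to 0.936 both before and after realignment. Fibroblast RNA is argued against by the GAS6 array, which had no fibroblasts. The GAS6 array differed from replicates 2 and 3 at 14 genes, against 3485 for the untreated array. A response shared by co-culture and GAS6 cannot be told apart from the array set, since set 1 holds no GAS6 array; replicate 1, the 1 co-culture in set 1, correlated with the GAS6 difference at 0.130. Different cells, passages or preparation under 1 cell line name may also differ in this way, given large differences such as those of IGFBP7 and CD34, and were not tested.

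CAF co-culture replicate 1 had lower DNA replication genes (median -1.47) and higher hypoxia genes (1.10) than the untreated array. Dilution by fibroblast RNA is argued against as the cause of the lower replication genes only on an assumption made after the data were seen. The assumption is that fibroblast markers would rise as a set by at least as much. Their rise would depend on their level in the fibroblasts, which was not measured. Only 12 of the 29 listed markers were measured, so the set is a partial check. Some were already high in untreated cells (FBN1 11.04, VCAN 9.55 and FN1 8.90), where added fibroblast RNA would show less. Others were low there, such as DCN (4.07) and TCF21 (3.92). The median difference of the fibroblast markers was 0 (SD of 12 members 0.663), and 0.28 (SD 0.89) over the 6 that were not exactly equal in the 2 arrays. Of these 6, 5 were higher, FN1 by 2.31, DCN by 0.41, VCAN by 0.30, LUM by 0.27 and SFRP2 by 0.08. Of the epithelial markers 9 of 12 were exactly equal, and the others, KRT18 (0.31), KRT7 (-0.0289) and EPCAM (-0.0878), are too few to weigh. The same marker values, 0.28 with an SD of 0.89, do not exclude fibroblast RNA as a source of the higher hypoxia genes, which stays open. A growth state of the culture that varies with or without fibroblasts, such as density or medium, cannot be told apart from a response to co-culture, since set 1 holds 1 untreated and 1 co-cultured array. Replicates 2 and 3 differed in the replication median by 0.414, the 1 pair of arrays of a single group and set. A response of the cancer cells to co-culture, which the design names, stays open and is a hypothesis that would need replicate untreated and co-cultured arrays processed together.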
